A study of Bacillus subtilis with 2 samples.

How the data were processed

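Genomic DNA of *Bacillus subtilis* strain MMB26 was measured on 2 spotted two-colour arrays, 1 per condition: cells growing in defined minimal medium before induction (0 min), and cells given 1% xylose for 60 min to overexpress dnaN. Per the labels, the Cy5 channel held the DNA of these cells. The Cy3 channel held reference DNA from dnaB mutant cells arrested for replication initiation, in which every locus is present at 1N. The reference was used as a common denominator and not as a sample. There are no replicates, so no significance test of the conditions was run, no p-value is given, and no difference has a replicate check.

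Per the file headers, the arrays were scanned at 635 and 532 nm on a GenePix 4000B scanner and quantified with GenePix Pro 3.0.6.90. The deposited intensity values are the mean brightness of each spot and the median local background in each channel. Per the file headers, the authors also computed a log2 ratio of Cy5 to Cy3 total spot signal, scaled by the summed signals of the Bacillus spots, and left out flagged, dim, E. coli and empty spots. Tested on the values, that signal was mean brightness times pixel number with no background subtracted. The deposited series table repeated this filtered log2 ratio in all 3976 values at 60 min and all 4035 at 0 min (tolerance 0.0051), with medians of -0.08 and -0.05, so its scale, direction and scaling are known.

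Each array held 4192 spots, of which 4114 were Bacillus genes, 70 were E. coli controls and 8 were other spots. The main value was log2 of Cy5 over Cy3 mean brightness, with no background subtracted, for Bacillus spots that had passed the authors' filter. It was centred on each array's median, with no loess or quantile step, and spots of 1 gene were averaged. The filter left out 86 Bacillus spots at 0 min and 143 at 60 min, and 3906 genes had a value on both arrays. Centring makes every value relative to the median gene, so a change of the whole chromosome cannot be seen.

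The files name no genome build. Gene order was therefore taken by symbol from the annotation of assembly ASM904v1, and no coordinates are given. Of 4053 genes on the array, 2991 (73.8%) were placed, and 2876 of these had a value on both arrays. The other 1062 had no unique match by symbol and entered only the gene lists and the ranking of single genes. An old symbol that now belongs to another gene would be misplaced. Positions run from dnaA, at the replication origin, to rtp, the gene of the replication terminator protein. The design fixed before the data were examined set windows and slopes by base distance. Gene order replaced it, so a window is 5% of the annotated genes on each side and a slope is per whole arm. Base distances were run as an alternative.

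The origin-to-terminus ratio is the median log2 ratio of the origin window minus that of the terminus window. Slopes were fitted by least squares, and profiles used 10 equal bins per arm. Departures were taken from a running median over 101 genes. The SPbeta prophage has 151 placed genes, more than this span, so its departure is fixed near 0 by construction and is not reported. Gene lists were fixed before the data were examined, and each list's median change was ranked among 10000 random lists of the same size matched on signal. These percentiles describe the 2 arrays and are not p-values for the conditions. The skin element list was meant to be limited to genes between its edges, but the edge genes were not found by symbol and the limit was not applied. Intervals are 95% bootstrap intervals over genes (1000 draws) and cover the scatter between probes only.

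Genes are named from the origin, terminus and xylose lists, from the 10 largest increases and 10 largest decreases, and from the 5 highest and 5 lowest residuals on each array. The ranked genes had to exceed the 10th percentile of signal in both channels of both arrays, which 3435 genes did. Segments of neighbouring genes were found by a rule chosen after the data were seen: a running median of the change over 7 placed genes beyond 0.25 in either direction, for at least 7 genes.

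Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. The procedure was tested on 50 simulated pairs of arrays with 2991 placed genes. A simulated change in origin-to-terminus ratio of 0.27 was recovered as 0.269 with an SD of 0.0165, and 100% of the genes of both simulated segments were found. The ratio was computed with the simulated segments left out, and every gene of a simulated segment had the same shift. The simulated rise segment was also longer than the 58 genes of the one found in the data. The simulation therefore does not cover a rise of that length, a segment inside the origin window or a segment with uneven changes.

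The alternatives were normexp background correction (limma, offset 50), plain background subtraction, loess, total-intensity scaling, other filters, the series table, other windows, bins and fits, and leaving out mobile elements or the segments. The median Bacillus spot was 30.4 times its background in Cy5 and 30.7 times in Cy3 at 0 min, and 31.2 and 35.0 times at 60 min. The number of arrays limits the precision.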

Results

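The arrays compared the copy number of each gene in cells before and 60 min after xylose was added to overexpress dnaN. dnaN encodes the sliding clamp, the ring that holds the replicative DNA polymerase on DNA. In an exponentially growing bacterial culture, genes near the origin are present in more copies than genes near the terminus, because replication starts at the origin and runs along both arms. The question set by the study's design was whether the share of origin DNA grows after dnaN overexpression. Values were obtained for 3970 genes at 0 min and 3921 at 60 min, and across genes the log ratios of the arrays correlated with r = 0.889 (genes are not independent replicates). Spots of the same gene differed by a median of 0.17 (log2, 57 genes) at 0 min and 0.15 (49 genes) at 60 min. All log ratios below are log2 and relative to the array median.

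Before induction, genes around the origin were 1.40-fold more abundant than genes around the terminus (log2 0.49, interval 0.44 to 0.56, 270 and 309 genes). At 60 min the ratio was 1.67-fold (log2 0.74, interval 0.68 to 0.80, 268 and 303 genes). The ratio was thus 1.19-fold higher after dnaN overexpression (log2 0.25, interval 0.19 to 0.30). The arrays differ in dnaN induction, in xylose and in time, so the effects of these cannot be told apart. Of the 266 origin genes measured on both arrays, 241 were higher at 60 min and 25 were lower, while of 301 terminus genes 63 were higher and 238 lower. Among all 2876 windows of 266 neighbouring genes, 20 had a higher median change than the origin window (0.13), and the highest of these, from deaD to ybcC, also reached 0.13. Windows start 1 gene apart and overlap, so such counts are not counts of separate regions. The window from deaD to ybcC itself runs across the origin. Without the 2 segments described below, 47 of 2791 windows of 208 genes had a higher median change than the origin window (0.086). The segment on the right arm, with 58 genes, made up part of the origin window. Without it the change was 0.19 (interval 0.12 to 0.21), which is 1.14-fold. With windows of 10% in place of 5% of the genes it was 0.15, and 0.11 when both segments described below were also left out.

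**Figure D1:**
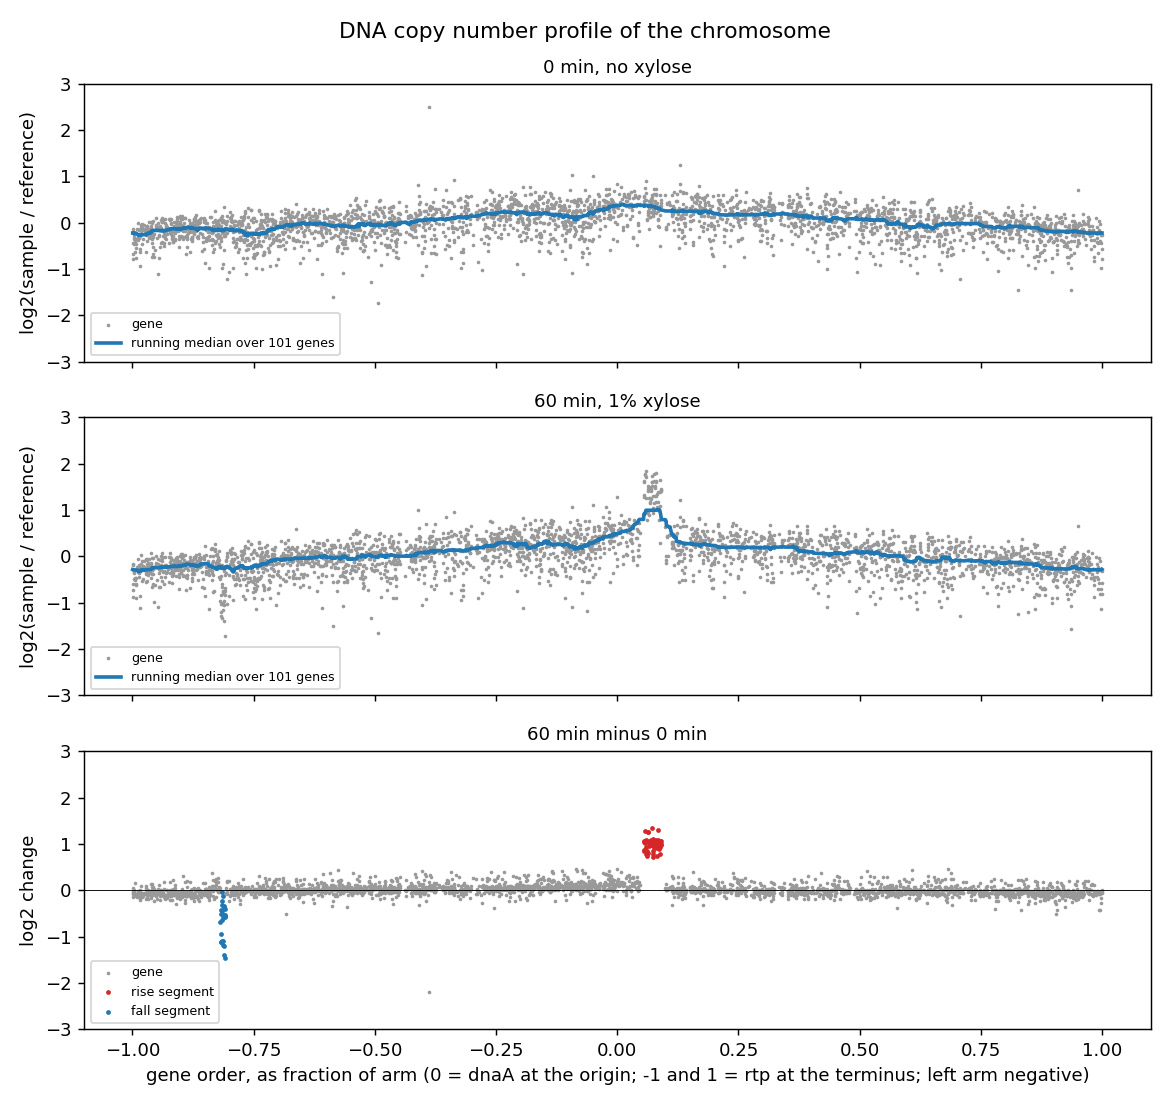
Log2 ratio of sample to 1N reference DNA for each placed gene at 0 min (top) and 60 min (middle), with the running median along the chromosome as a line, and the log2 change of each gene (bottom), against gene order from the origin at 0 to the terminus at -1 and 1. A segment of 58 genes on the right arm stands above its neighbours at 60 min, and a segment of 27 genes on the left arm lies below them.

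The list of genes next to the origin is not separate from the window, which holds all 14 of its placed measured genes. Of its 22 measured members, dnaN included, 19 were higher at 60 min. The median change was 0.12, above all of the 10000 random lists (percentile 100), which were matched on signal and not on position. Outside dnaN, examples were recF, a recombination gene (0.25), gyrB, which encodes a gyrase subunit (0.12), yabA, which encodes a negative regulator of replication initiation (0.12), and serS, a tRNA synthetase gene (0.14). The gene of the initiator protein, dnaA, was at -0.03 on the 0 min array and -0.05 on the 60 min array, a change of -0.03, and soj changed by -0.03. The exception in size was spoIIIJ, with a change of -0.86. The terminus list also holds codV and ripX, which lie outside the terminus window. Of its 10 genes 2 were higher and 8 lower, with a median change of -0.05 (percentile 5.39). Among them rtp changed by 0.01, proJ by -0.05, parC, which encodes a topoisomerase subunit, by -0.09, and ggt by -0.42.

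Along the chromosome the log ratio fell from origin to terminus on both arms and both arrays. Per whole left arm the slope was -0.48 (interval -0.53 to -0.43) at 0 min and -0.67 (-0.73 to -0.62) at 60 min. On the right arm it was -0.60 (-0.65 to -0.55) and -0.95 (-1.03 to -0.87). The difference between the arrays was -0.20 (-0.22 to -0.18) on the left arm and -0.34 (-0.39 to -0.29) on the right. Without the segments of 58 and 27 genes these differences were -0.16 (-0.18 to -0.14) and -0.11 (-0.14 to -0.09), so on the right arm the segment set most of the value. With a Theil-Sen fit over all genes the right arm's difference was -0.14, and without the genes within 5% of the origin and of rtp it was -0.07.

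By distance, the left arm changed gradually. When each arm was cut into 10 bins, the left arm's median change was 0.08 in the bin nearest the origin, where 143 of 162 genes were higher, then 0.07 and 0.04 in the bins that follow. It was -0.07 in the bin nearest the terminus, where 28 of 167 genes were higher. On the right arm the bin nearest the origin had a median change of 0.73 over 113 genes, and 0.11 over the 55 genes outside the segment. With 5 bins it was 0.06 and with 20 bins 0.11. In bin 2 of the right arm 67 of 134 genes were higher, and the bin nearest the terminus was at -0.06.

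**Figure D2:**
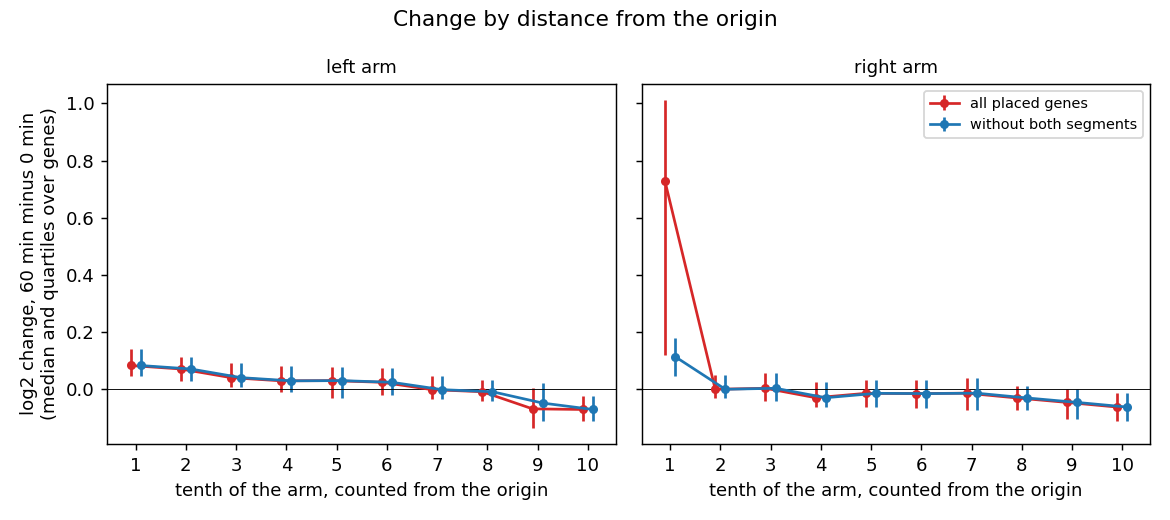
Median log2 change (60 min minus 0 min) in 10 bins of the left and right arm, counted from the origin, with quartiles over genes as bars, for all placed genes and without the segments of 58 and 27 genes. The right arm's value nearest the origin is 0.73 with the segment and 0.11 without it, and the values nearest the terminus are -0.07 on the left and -0.06 on the right.

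Of the 10 largest increases among genes above the signal filter, 8 lay in 1 block on the right arm, from ctsR to kbaA, found after the data were seen. All 58 of its measured genes were higher at 60 min, with a median change of 1.01 (2.02-fold), quartiles of 0.93 and 1.05 and a range of 0.72 to 1.35. It holds 31 genes of ribosomal proteins (median change 1.00) and 27 other genes (1.02). rplC, rplA, rplK and rpsC, which encode ribosomal proteins, changed by 1.35, 1.26, 1.25 and 1.11. radA, a DNA repair gene, changed by 1.28, fusA (elongation factor G) by 1.09, secY (the protein translocation channel) by 1.08, and cysS (a tRNA synthetase) by 1.08. ybaF (1.11) and ybxB (1.08), which were not placed, were the other members of these 10. At 0 min the block had a median log ratio of 0.35, against 0.36 for the 20 genes before it and 0.26 for the 20 after it.

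The block's edges were sharp. lysS, the measured gene before it, changed by 0.11 and ybaR, the one after it, by 0.05. The 53 genes between dnaA and the block, which lie nearer the origin, had a median change of 0.11, which is -0.90 relative to the block. In the annotation the gap before the block holds the rrnJ and rrnW ribosomal RNA operons (6 rRNA genes), and the gap after it holds rrnI, rrnH and rrnG (9 rRNA genes). The block's spots lay in 29 of the 32 blocks of the slide, and the 386 spots next to them had a median change of -0.01.

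**Figure D3:**
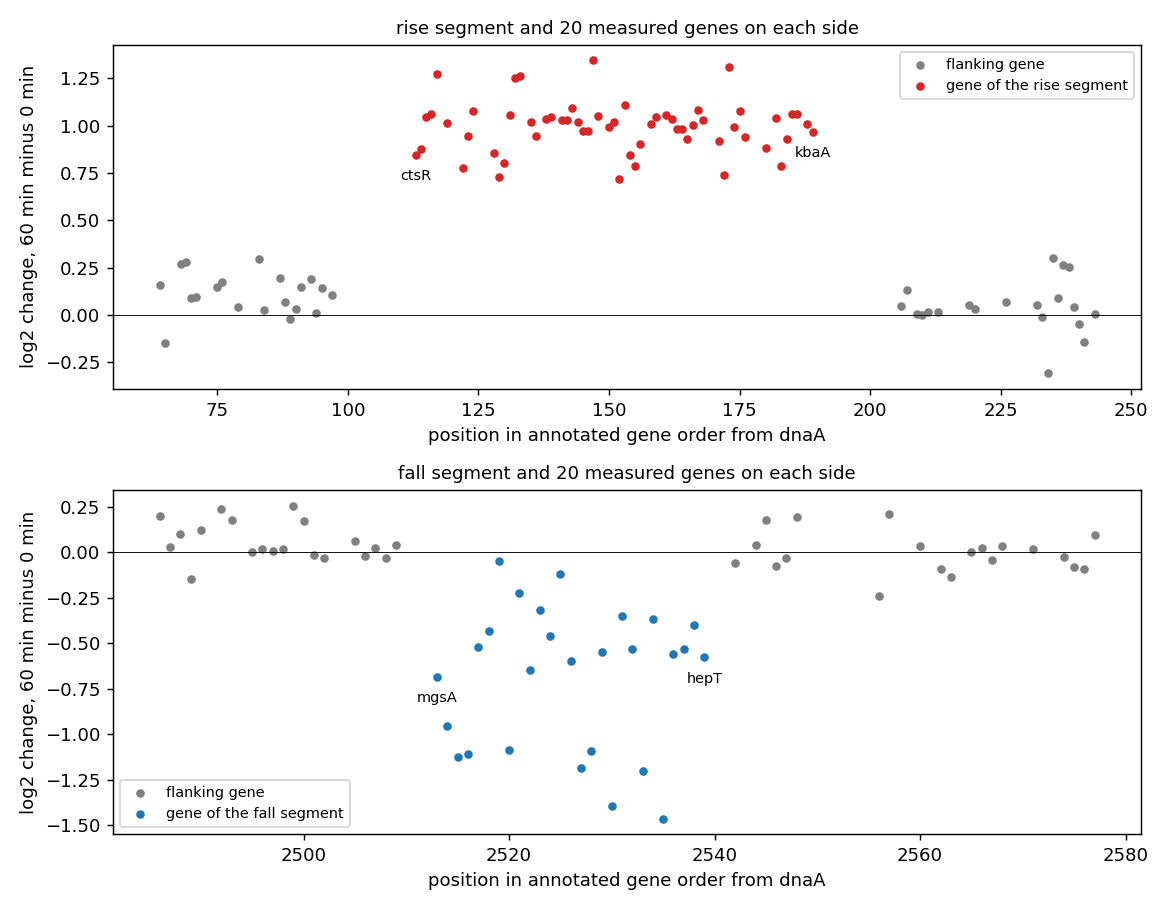
Log2 change (60 min minus 0 min) of each measured gene of the rise segment (top, ctsR to kbaA) and the fall segment (bottom, mgsA to hepT), with 20 measured genes on each side, against annotated gene order from dnaA. The rise segment lies between 0.72 and 1.35 with sharp edges, and the fall segment is spread from -0.05 to -1.46.

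Of the 10 largest decreases among genes above the signal filter, 8 lay in another block, on the left arm, from mgsA to hepT. All 27 of its genes were lower at 60 min, with a median change of -0.56 (0.68-fold), quartiles of -1.09 and -0.42 and a range of -1.46 to -0.05. aroB, a gene of the shikimate pathway, changed by -1.46, and trpF, trpE and trpA, of tryptophan synthesis, by -1.39, -1.20 and -1.09. hisC, of histidine synthesis, changed by -1.19, qcrB, a cytochrome gene, by -1.09, and dapB, of lysine synthesis, by -0.95. ypjC was at -1.11, and ypjG (-1.76) and ypjH (-0.87), which were not placed, were the other members of these 10. paiB is not among the block's 27 genes, fell short of the signal filter and is named after its values were seen. It had a log ratio of 2.49 at 0 min and 0.29 at 60 min, a change of -2.20. The block's flanking genes birA and mtrB changed by 0.04 and -0.06, and no rRNA gene lies in the gaps at its ends. The 182 spots next to the block's spots on the slide had a median change of -0.01.

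dnaN itself, measured on 1 spot, had a log ratio of 0.84 before induction and 1.29 at 60 min, a change of 0.45. The processing alternatives were not run for this single gene. It already exceeded the running median of its neighbourhood by 0.47 at 0 min, and by 0.80 at 60 min. Of the 5 xylose genes, xylR, which encodes the xylose repressor, stood apart: it was at 0.71 and 0.65, while xylA was at -0.44 and -0.52, xylB at -0.08 and -0.27, xynB at -0.38 and -0.43, and xynP at -0.50 and -0.62. All 5 were lower at 60 min, with a median change of -0.08 (percentile 4.04) that was -0.15 with normexp background correction. These 5 genes lie within the terminus window, where the median change was -0.06 and 238 of 301 genes were lower. The random lists were matched on signal and not on position, so the percentile does not set the xylose genes apart from their surroundings. Of 5 loci commonly used to integrate constructs 3 were higher (median 0.08, percentile 90.2), with a median of 0.019 without the filter on spots, and amyE had no value after the authors' filter.

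Of 24 genes of the replication machinery at any position 14 were higher, with a median change of 0.06 (percentile 98.9) that was 0.021 with loess and 0.028 with normexp. Of 9 genes next to DnaA-box clusters, the binding sites of the initiator, 6 were higher, with a median of 0.06 (percentile 92.6). Both lists hold dnaN and other genes near the origin.

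Mobile elements can be lost or excised apart from the chromosome. In the SPbeta prophage, which lies near the terminus, 144 of 169 genes were lower at 60 min, with a median change of -0.09 (percentile 0) that was -0.15 with normexp. The random lists were not matched on position. In the terminus window, which holds part of the prophage, the median change was -0.06 and 238 of 301 genes were lower. The percentile therefore does not set SPbeta apart from its surroundings. In the conjugative element ICEBs1 7 of 21 genes were higher (median -0.02, percentile 21.4), in the PBSX prophage 13 of 28 (median -0.0036, percentile 40.8), and in the skin element 23 of 50 (median -0.0057, percentile 37.6). The sign of the last pair turned with loess, to 0.016 for PBSX and 0.014 for skin, and that of PBSX also with the background subtracted, to 0.0018. The median residual from the running median was 0.036 at 0 min and -0.016 at 60 min over 11 placed ICEBs1 genes. Over 43 placed skin genes it was -0.0079 and -0.019. Over the 28 PBSX genes measured on both arrays it was 0.073 at 0 min and 0.18 at 60 min. The bootstrap interval of this 60 min value had a half-width of 0.16. Over all PBSX genes with a value at 0 min the residual was 0.043. With a running median over 51 genes it was 0.046 over all genes at 0 min and 0.084 at 60 min.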

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

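Alternatives that leave out the segments, use base distances, subtract the background, join 2 choices, take the median of single-gene changes, or concern the segments or named genes under plain subtraction were chosen after seeing the data. Not counted here are 65 values whose outcome was fixed, since the setting cancels, removes none of the genes concerned or repeats another, or the SPbeta residual is near 0 by construction. Of the other 192 values for 29 comparisons, 147 moved by less than the half-width of the bootstrap interval over genes, used in place of a replicate spread, and 45 moved by more. The sign changed in 4, all near 0: the PBSX median change was 0.016 with loess and 0.0018 with the background subtracted, that of skin was 0.014 with loess, and the skin residual at 0 min was 0.0069 with a running median over 51 genes. For 32 named genes, 169 of 192 values moved by less than 0.074, and 8 values of 5 genes changed sign. These 192 include settings that are no separate check of a single gene. Total-intensity scaling and no filter on spots shifted every named gene by the same amount, less than 0.074. The series table differed by rounding and centring only. The change in origin-to-terminus ratio was positive under all 18 alternatives counted, from 0.11 to 0.36. The series table is among these 18 and among the values for the 29 comparisons. It holds the same ratio rounded, so its value of 0.245 could hardly differ and is no separate check. Leaving out background subtraction is the main setting, so it gave no separate value. The causes of the shifts were not tested, except where genes were left out. No paired analysis was possible because each condition has 1 array. The median spot lay about 30 times above its background, and the error of a single array per condition was not measured. At 0 min the origin-to-terminus ratio was 0.63 with normexp, 0.58 with windows of 2.5% and 0.41 with windows of 10% of the genes. At 60 min it was 0.94 with normexp, 0.67 with loess, 0.56 with windows of 10%, 0.84 with the mean, and 0.65 without the rise segment or without both segments. The change between them was 0.31 with normexp, 0.17 with windows of 2.5%, 0.15 with windows of 10% and 0.36 with the mean. It was 0.19 without the rise segment, without both segments, or as the median of single-gene changes. Without both segments it was 0.16 with windows of 2.5%, 0.11 with windows of 10% and 0.16 with the mean. With normexp the left arm's slope was -0.66 at 0 min and -0.89 at 60 min, the right arm's -0.70 and -1.10, and the differences -0.25 and -0.40. With loess the left arm's slope was -0.41 and -0.58 and its difference -0.17, and without mobile elements its 0 min slope was -0.53. The Theil-Sen difference was -0.17 on the left and -0.14 on the right, where the 60 min slope was -0.83. Without the origin and terminus windows the right arm was at -0.64 at 60 min and its difference at -0.072. Without the rise segment or both, these were -0.70 and -0.11, and without both the left arm's difference was -0.16. The right arm's change nearest the origin was 0.061 with 5 bins, and 0.11 with 20 bins or without both segments. With normexp the median changes of the origin, SPbeta and xylose lists were 0.090, -0.15 and -0.15, and with loess that of SPbeta was -0.066. The rise segment changed by 1.16 with normexp, 0.98 with total-intensity scaling and 1.05 with the background subtracted. All 58 of its genes and 26 of the 27 genes of the fall segment were found again with normexp, which gave 5 segments in place of 2, while the filter on dim genes kept 38 and 22 of them.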

Other observations

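The tests of an extra segment copy, of the reference and of loss for the fall, and of both explanations for dnaN and xylR were chosen only after the result was seen. The tests of carried-over RNA and of the reference for the rise were written before their own values, but after the rise had been seen. Of 5 Bacillus genes on spots outside the comparisons, 2 exceeded every E. coli control spot in Cy5: yosO had a Cy5 intensity of 12490 at 0 min and 14286 at 60 min, and ygaH 3140 and 3940, against highest control spots of 1485 and 2390. yrvP (804 and 897), yitX (1419 and 1720) and yraC (1297 and 1308) stayed below them, as did lacZ and gfpmut2.

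The 58 genes between the rrnW and rrnI operons changed by a median of 1.01 at 60 min. RNA carried over into the sample DNA would raise ribosomal protein genes everywhere, but the 15 placed outside the segment changed by a median of 0.046 (quartiles -0.02 and 0.16). A lower reference signal stays open in part: relative to all genes the segment's Cy3 signal changed by -0.27 and its Cy5 signal by 0.69, between the bounds set beforehand. An extra copy of a segment bounded by rRNA operons, possibly by recombination between them, is a candidate explanation that was not independently tested: 1 of 2876 placements of an equally long run (0.0348%) has rRNA genes in both end gaps, but that is the observed one, which prompted the explanation. Whether it arose with dnaN overexpression or was present in the 60 min culture for another reason was not tested, with 1 array per condition.

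The 27 genes from mgsA to hepT changed by a median of -0.56. A higher reference signal alone is argued against by the Cy5 signal, which changed by -0.53 relative to all genes (quartiles -0.90 and -0.33). The Cy3 signal of the segment changed by 0.18 (quartiles -0.02 and 0.31), so a part played by the reference stays open. Loss of the segment from all cells was first to be judged by its lowest spot, which had 0.763 times the Cy5 signal of the highest E. coli spot, and this decided nothing, with 24 of 28 spots above that control. A second criterion, set once those values were known, was the median spot, at 19.3 times the E. coli median. The typical spot of the segment thus kept signal above the typical control. As the outcome was known when this criterion was set, it is a description and no test of loss from all cells. For loss from a share of cells, alike for every gene, the interquartile range of the changes was compared with that of the rise segment. It was 5.34 times as large, so the measured changes were uneven. Signal from other DNA was not measured for each probe and could make a like loss look uneven. Loss from a share of cells therefore stays open, as does what lowered these genes unequally.

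dnaN and xylR had high log ratios on both arrays. Extra copies on an integrated xylose-inducible construct, which commonly carries xylR, may account for this, and so may offsets of their probes, and both stay open. At most 1.84% of placed genes had residuals as high as either gene on either array, and 8 of 2876 (0.278%), dnaN and xylR included, reached the lower of both on both arrays. These shares restate how high the pair is and decide nothing. Another gene, ybfA, exceeded xylR on both arrays, with residuals of 0.996 at 0 min and 0.915 at 60 min, against 0.915 and 0.909 for xylR. The labels used here do not describe the construct. The change of dnaN from 0 to 60 min, 0.45, was reached or exceeded by 1 other placed gene outside the segments, xre (0.47), and by 17 unplaced genes, whose position relative to the segments is not known here.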
